A study of Homo sapiens with 12 samples.

How the data were processed

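KYSE150 cells, an established human line of oesophageal squamous cell carcinoma, were cultured with or without galectin-9, a lectin that binds beta-galactosides. Per the labels' protocols, the dose was 100 nM and the exposure lasted 6 h, in medium with a low serum content. Total RNA was labelled with Cy5 and hybridised to 3D-Gene human miRNA arrays, 1 sample per array. There were 6 control and 6 galectin-9 arrays, numbered 1 to 6 in each group. The labels do not say whether the numbered samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

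Each deposited array file lists 3200 spots with a raw Cy5 intensity, a background-subtracted intensity and a globally normalised intensity, per the file headers. The columns hold linear fluorescence in arbitrary units. Among the spots were 2565 human miRNA probes, of which 15 name several miRNAs, and 320 blank spots. Comparison of the columns showed how the authors' values were made. The subtracted background equals the mean of the blank spots after trimming 5% at each end. A background-subtracted intensity is listed only where the raw intensity exceeds that mean by more than 2 SD of the trimmed blanks. The global normalisation sets the median of the listed probes to 25. The authors' deposited series table holds 891 probes on a linear intensity scale, with the same sorted values on every array. Those values match the mean of the sorted background-subtracted intensities over the probes listed on all arrays, with a largest deviation of 0.102%. The table is therefore quantile-normalised and not centred, with a median of 12.3 in every column. The scanner and its software are not given in the sources used here.

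The file's own limit served as the detection call. Raw intensity minus the array's background was quantile-normalised over all human miRNA probes with limma 3.58.1 in R 4.3.3. Values below the limit were then set to the array's lowest detected normalised value, and log2 was taken. Quantile normalisation that treats undetected probes as missing at random was not used, since the missing values are the dim ones. The 6 human miRNA spots that the files mark as not good were left out. Probes detected on at least 6 of the 12 arrays were tested, 1734 in all, and 192 probes were detected on no array. The test was limma's lmFit and eBayes for galectin-9 minus control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Quantile normalisation gives probes of fixed rank a fixed value, so the brightest probes differ between arrays only where they swap ranks.

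The numbers of detected probes ranged from 934 on control 6 to 2045 on galectin-9 replicate 1. The number of arrays limits the precision. Over the 891 probes detected on all arrays, log2 intensities of 2 arrays correlated at 0.978 or higher within the control group, 0.980 or higher within the galectin-9 group and 0.975 or higher between groups. No arrays held identical values.

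File names carry a code shared by 4 arrays, taken here as the slide, and a number from 1 to 4, taken as the position. Each of the 3 slides held 2 control and 2 galectin-9 arrays, with replicates 1 and 2 on slide 1, 3 and 4 on slide 2, and 5 and 6 on slide 3. Control arrays always had an odd position and galectin-9 arrays an even one, so the parity of the position and the treatment cannot be told apart. Equal replicate numbers sat at neighbouring positions of a slide. Whether the numbers pair the samples was checked through the correlation of deviations from the group means. Across probes, this correlation was above 0.1 for 6 of 6 pairs, from 0.171 to 0.527, while arrays with different numbers had a median of -0.04. For control 2 it was 0.205 with galectin-9 replicate 2 and up to 0.208 with a galectin-9 array of another number. Neighbouring positions could also give such correlations, so they do not show that the samples were paired. The numbers were nevertheless taken as pairs, and a fit with the replicate number as a block is given where it changes a call. In principal components over the same probes, the mean score differed between slide 3 and the other slides on component 1 (exact permutation p = 0.00808), with both arrays of replicate number 5 farthest from the rest. It differed between positions 1 and 2 and positions 3 and 4 on component 2 (exact permutation p = 0.00649), and between the groups on component 3 (exact permutation p = 0.00433). The scores of single arrays overlapped in each case. Each contrast was tested on each of the 3 components, without adjustment. The groups showed no clear difference in mean score on components 1 and 2 (exact permutation p = 0.532 and 0.152). Positions 1 and 2 hold replicates 1, 3 and 5 and positions 3 and 4 hold replicates 2, 4 and 6, so these positions and replicate numbers cannot be told apart.

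The design, the 25 miRNA lists and the rule for naming miRNAs were fixed before the data were examined. Named are up to 12 probes with the largest increase and 12 with the largest decrease among those that passed and were detected on all 12 arrays, and the 3 dimmer ones with the smallest p per direction. Where none passed in a direction, the 5 with the smallest unadjusted p are given as values. Also covered are the 3 members of each list with the smallest p, miR-21-5p, miR-210-3p and miR-1246, and the 5 brightest probes. The rule covers 73 probes, of which the text gives a selection.

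Lists were tested with limma's camera, with a preset correlation of 0.01 and, as an alternative, an estimated one, over the 24 lists with at least 3 tested probes. Probes with a missing spot were left out of this test. Members were also adjusted over their list alone, with no further adjustment for the number of lists. A probe belonged to a list by its name without arm and copy number. The lists cover the let-7, miR-200, miR-15/16, miR-29, miR-30, miR-181 and miR-221 with miR-222 families and the miR-17 (with paralogs), miR-23/27/24 and miR-99, miR-100 and miR-125 clusters. Others hold p53-induced, inflammatory and hypoxia-induced miRNAs, miRNAs described as raised or lowered in oesophageal squamous carcinoma, and markers of squamous epithelium. Markers of other cell types covered blood cells, muscle, mesenchyme, liver with neuron and endothelium, and pluripotent cells. The imprinted cluster of chromosome 14 and the placental cluster of chromosome 19 were included, as were miRNAs numbered up to 500 and those numbered from 3000. Gene symbols, hosts and neighbours of miRNA genes were looked up by name in a RefSeq gene table of GRCh38.p14, which matched 8 of 9 miRNAs. No coordinates are given, since the files name no genome build.

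The steps were tested on simulated arrays built from the measured means, spread and detection limits for galectin-9 against control, with 200 changed probes in each of 10 runs additive noise of 1 SD of the blanks, and a mean of 1735 probes tested. Of the simulated changes, 39.2% of those of 1.5-fold and 77.3% of those of 2-fold were recovered, and 4.76% of calls were false, with 0 in the wrong direction. With the replicate block the recovered shares were 29.1% and 69.9%. With noise of 0.5 SD in place of 1 SD, the shares were 60.1% and 92.1% without the block, so recovery depends on the noise assumed. With noise of 1 SD, a list shifted by 0.2 on the log2 scale was called in 5 of 10 runs. The simulated noise was independent between probes and arrays, without the pair and slide differences of the measured arrays. The recovered shares, the false share and the list calls may therefore differ on the measured arrays. Alternatives covered background correction, normalisation, the source of the values, the filter on dim probes, the floor, the variance model, array weights, replicate and slide blocks, omitted slides and arrays, and an unmoderated test.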

Results

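The levels of human miRNAs were measured on 12 single-colour arrays of KYSE150 oesophageal squamous carcinoma cells, 6 without and 6 with galectin-9 for 6 h at 100 nM. The series concerns miRNAs linked to the action of galectin-9 against this tumour type, and its design implies a single contrast, treated against untreated cells. Of 2565 human miRNA probes, 891 were detected on all 12 arrays and 1734 on at least 6. The brightest probes were miR-4454, miR-7975, miR-7977, miR-1260b and miR-4284.

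The arrays of the 2 groups were first compared before normalisation. Control arrays had 1559 ± 373 detected probes and galectin-9 arrays 1810 ± 202 (SD, n = 6 each), a difference within the spread between arrays (exact permutation p = 0.180, two-sided). Within slides, galectin-9 arrays had 105.5 more detected probes on slide 1, a difference of -58.5 on slide 2 and 706 more on slide 3, where control 6 had only 934. The median background-subtracted intensity over probes detected on all arrays was 12.1 ± 2.74 in control and 12.5 ± 1.85 in galectin-9 arrays (SD, n = 6 each, exact permutation p = 0.755). These are 2 of 7 array measures compared, and the adjusted p was 0.432 for detected probes and 0.755 for the median intensity. No probe was detected on all 6 arrays of a group and on 0 of the other.

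**Figure D1:**
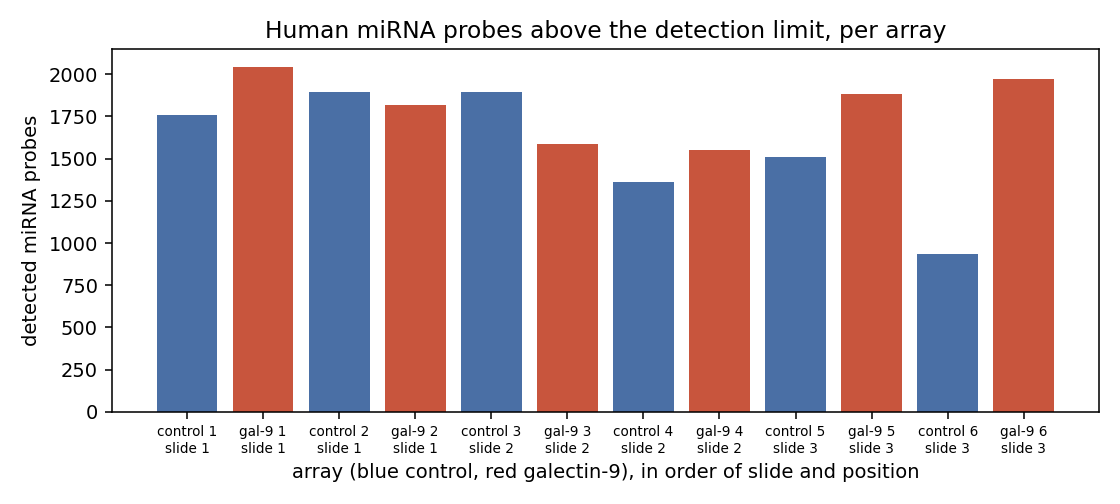
Number of human miRNA probes above the detection limit (vertical axis) on each of the 12 arrays, ordered by slide and position, with control arrays in blue and galectin-9 arrays in red. Control 6 has 934 detected probes, the fewest, and galectin-9 replicate 1 has 2045, the most.

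With galectin-9, 3 of the 1734 tested miRNA probes were higher and 0 lower at the threshold. Control arrays always lay at odd and galectin-9 arrays at even positions of a slide, so this and every other difference between the groups cannot be separated from an effect of position parity. The largest change was in miR-6131 (MIMAT0024615), whose gene lies within ROPN1L: its log2 intensity was 4.60 ± 0.22 in control and 5.77 ± 0.26 in galectin-9 cells (SD, n = 6 each). This is a 2.26-fold rise (95% interval 1.83 to 2.78, limma adjusted p = 0.00262). The passenger arm miR-222-5p (MIMAT0004569), from the hairpin next to miR-221 in the host transcript MIR222HG, rose 1.82-fold (1.51 to 2.19, limma adjusted p = 0.0101). Its log2 intensity went from 3.01 ± 0.21 to 3.87 ± 0.20. miR-582-5p (MIMAT0003247), from a hairpin within the phosphodiesterase gene PDE4D, rose 1.52-fold (1.31 to 1.77, limma adjusted p = 0.0290). All 3 were detected on all 12 arrays and were higher in 6 of 6 pairs of equal replicate number.

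Within slides 1, 2 and 3, the log2 difference was 1.41, 1.17 and 0.95 for miR-6131, and 0.86, 0.87 and 0.86 for miR-222-5p. For miR-582-5p it was 0.57, 0.47 and 0.78. With the replicate number as a block, only miR-6131 passed (limma adjusted p = 0.0360), against 0.0950 for miR-222-5p and 0.130 for miR-582-5p. miR-582-5p also lost its call when any of 8 single arrays was left out (controls 1, 4, 5 and 6 and galectin-9 replicates 3 to 6), with an adjusted p from 0.0557 to 0.106. When slide 1, 2 or 3 was left out, which leaves 8 arrays, none of the 3 passed. Their log2 differences were then 1.11, 1.17 and 1.26 for miR-6131, 0.87, 0.86 and 0.87 for miR-222-5p, and 0.63, 0.67 and 0.52 for miR-582-5p. The smallest adjusted p for miR-6131 was 0.0868, for miR-222-5p 0.107 and for miR-582-5p 0.231.

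Over these 1734 probes, limma called 0 lower. With array-specific floors, 149 probes had a lower level and 73 a higher one at an unadjusted p under 0.05. Chance would give 86.7 of 1734 for both directions together, so each direction alone is to be set against a smaller number. Over the 891 probes detected on all arrays, 78 were lower and 78 higher at this unadjusted threshold. Chance would give 44.55 there, again for both directions together. An unmoderated test called 2 lower. The 5 with the smallest unadjusted p all had an adjusted p of 0.140. Their log2 differences were -0.47 for miR-4723-5p, -0.51 for miR-519a-3p, -0.96 for miR-150-3p, -0.74 for miR-3198 and -0.32 for miR-4664-5p. Of these, miR-150-3p was detected on 7 and miR-3198 on 9 of the 12 arrays, so their differences rest partly on the floor. In control 6 both were set to its floor of 2.44, which was the highest control value of each.

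Among the 891 probes detected on all arrays, 9 passed, 6 higher and 3 lower, and these include the 3 miRNAs above. The others, named after their values were seen, were miR-19a-3p (log2 difference 0.39, adjusted p = 0.0290), miR-335-5p (0.43, adjusted p = 0.0316) and miR-99a-5p (0.56, adjusted p = 0.0397) toward higher levels. miR-4723-5p (adjusted p = 0.0290), miR-4664-5p (adjusted p = 0.0290) and miR-519a-3p (adjusted p = 0.0307) passed toward lower levels. miR-19a belongs to the miR-17 cluster in MIR17HG, miR-335 lies within the imprinted gene MEST, and miR-99a lies next to let-7c in MIR99AHG. With the replicate block, the same filter gave 22 calls, 14 higher and 8 lower, which include these 9. The combination of block and filter was chosen after the data were seen.

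Of the miRNAs named in any case, miR-21-5p, often raised in carcinomas, had a log2 difference of 0.42 and was higher in 6 of 6 pairs but did not pass (adjusted p = 0.201). The hypoxia marker miR-210-3p differed by 0.09 (adjusted p = 0.805) and miR-1246 by 0.06 (adjusted p = 0.829).

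**Figure D2:**
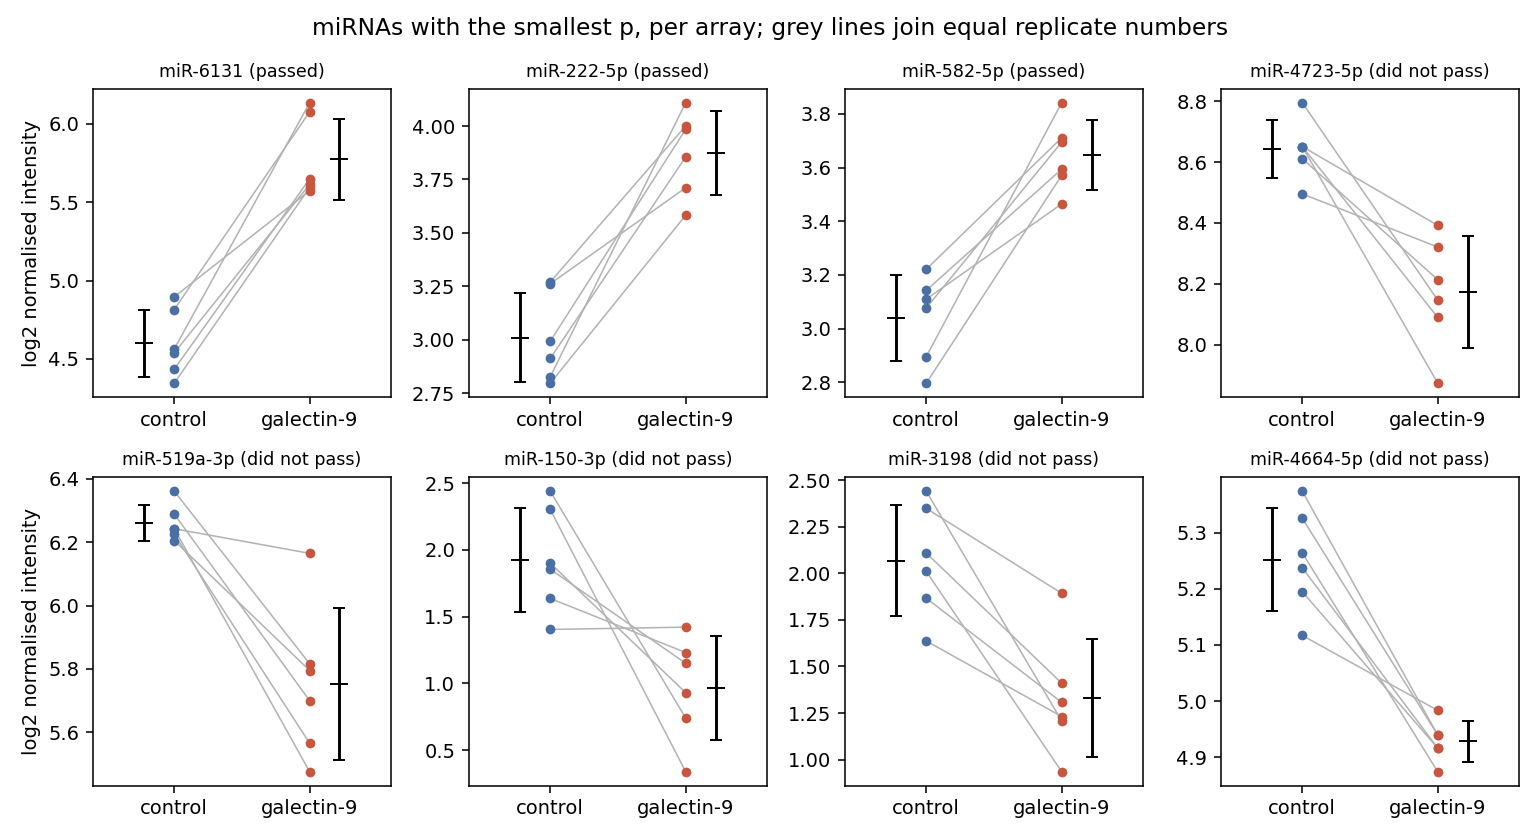
Log2 normalised intensity (vertical axis, a separate range per panel) of 8 miRNAs in control (blue) and galectin-9 (red) arrays. Each point is 1 array, grey lines join equal replicate numbers, and the black bar gives the mean ± SD of 6 arrays. miR-6131, miR-222-5p and miR-582-5p passed the test and lie higher with galectin-9 in 6 of 6 pairs, while the 5 lower ones did not pass over the 1734 probes.

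The family of miR-221 and miR-222, which targets the cell cycle inhibitor CDKN1B, passed the list test toward higher levels (camera adjusted p = 0.000152), with 4 of 4 probes above 0. The call was lost with an estimated correlation (adjusted p = 0.0962). Over all probes tested, 1 member passed, and 2 passed when adjusted over the list alone. These were miR-222-5p and miR-221-3p, whose log2 difference was 0.34. The mean log2 difference of the 4 probes was 0.38, from 0.19 to 0.55 over the 6 pairs (exact sign-flip p = 0.0312, the smallest that 6 pairs allow). It was 0.18 with normexp and 0.53 without normalisation. The other arms had smaller log2 differences than miR-222-5p, with 0.20 for miR-222-3p and 0.12 for miR-221-5p.

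The miR-17 cluster, whose host gene is MIR17HG, and its paralogs, polycistrons linked to proliferation, also passed toward higher levels (camera adjusted p = 5.27e-05, and adjusted p = 0.376 with an estimated correlation). Of 26 tested probes, 20 lay above 0, with a mean log2 difference of 0.07. All 18 of those detected on all arrays did, with a mean of 0.20, from 0.13 with normexp to 0.35 without normalisation. These 18 probes are not independent, with an estimated correlation of 0.348 between them. Paralogs of similar sequence can share signal between probes, which was not tested. Dimmer members below 0 include miR-92a-1-5p (-0.80) and miR-106a-3p (-0.72), whose values rest on the floor. No member passed over all probes, and 1, miR-19a-3p, passed when adjusted over the list alone (adjusted p = 0.0170, and 0.0680 with the replicate block). miR-17-5p (0.28) and miR-18b-5p (0.26) had the next smallest p. The mean of the 18 probes was above 0 in 6 of 6 pairs, from 0.02 to 0.36.

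The miR-29 family, which targets MCL1 and collagens, passed with 7 of 7 probes above 0 (camera adjusted p = 0.00922, and adjusted p = 0.114 with an estimated correlation). In the fit over 1734 probes, no member passed over all probes or when adjusted over the list alone, and the log2 differences were 0.39 for miR-29a-5p, 0.28 for miR-29c-3p and 0.16 for miR-29a-3p. In the same fit with the replicate block, miR-29a-5p passed when adjusted over the list alone (adjusted p = 0.0352), and without the block 2 members did among probes detected on all arrays. This list also lost its call without control 6 (adjusted p = 0.113), and with a floor common to all arrays (adjusted p = 0.183).

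miRNAs described as raised in oesophageal squamous carcinoma passed toward higher levels (camera adjusted p = 0.00511, and adjusted p = 0.471 with an estimated correlation). Here 16 of 26 tested probes lay above 0, and 14 of the 15 detected on all arrays. No member passed over all probes, and 2 passed when adjusted over the list alone, miR-21-5p upward and the dim miR-373-5p downward (log2 difference -0.66). Under the block these 2 no longer passed (adjusted p = 0.0622 each), and miR-31-3p did (adjusted p = 0.00737). The list shares miR-25, miR-93 and miR-106b with the miR-17 cluster list. miRNAs described as lowered in these tumours did not pass (adjusted p = 0.698). Their member miR-99a-5p (0.56) passed when adjusted over the list alone. The block added miR-143-3p (-0.71, adjusted p = 0.0267 over the list alone), detected on 4 control and 4 galectin-9 arrays, whose value rests on the floor.

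Early-numbered miRNAs, mostly conserved, passed toward higher levels relative to other probes (camera adjusted p = 0.00119, and adjusted p = 0.488 with an estimated correlation), although their median was -0.01 and their mean -0.04. In the fit over 1734 probes, miR-222-5p was the only member that passed, over all probes and when adjusted over the list alone. With the replicate block, miR-31-3p, miR-296-3p (log2 difference -0.81) and miR-215-5p also passed over the list alone, with adjusted p of 0.0372, 0.0372 and 0.0419. Among those detected on all arrays, 143 of 227 lay above 0, with a mean of 0.07, from 0.03 with normexp to 0.20 without normalisation, where 194 of 227 did. Late-numbered miRNAs, mostly described from deep sequencing, did not pass as a list (adjusted p = 0.218), with miR-6131 as the only member past the threshold in that fit, over all probes and when adjusted over the list alone. Of the late-numbered probes detected on all arrays, 197 of 515 lay above 0, with a mean of -0.04, which turned to 0.06 without normalisation (330 of 515 above 0). The list passed toward lower levels over those probes (adjusted p = 0.00226, and adjusted p = 0.306 with an estimated correlation). Over all 891 probes detected on all arrays, 7 of 19 lists passed, the 5 called ones, the late-numbered list and the miRNAs lowered in oesophageal tumours (toward higher levels, adjusted p = 0.00896), and 0 passed with an estimated correlation.

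**Figure D3:**
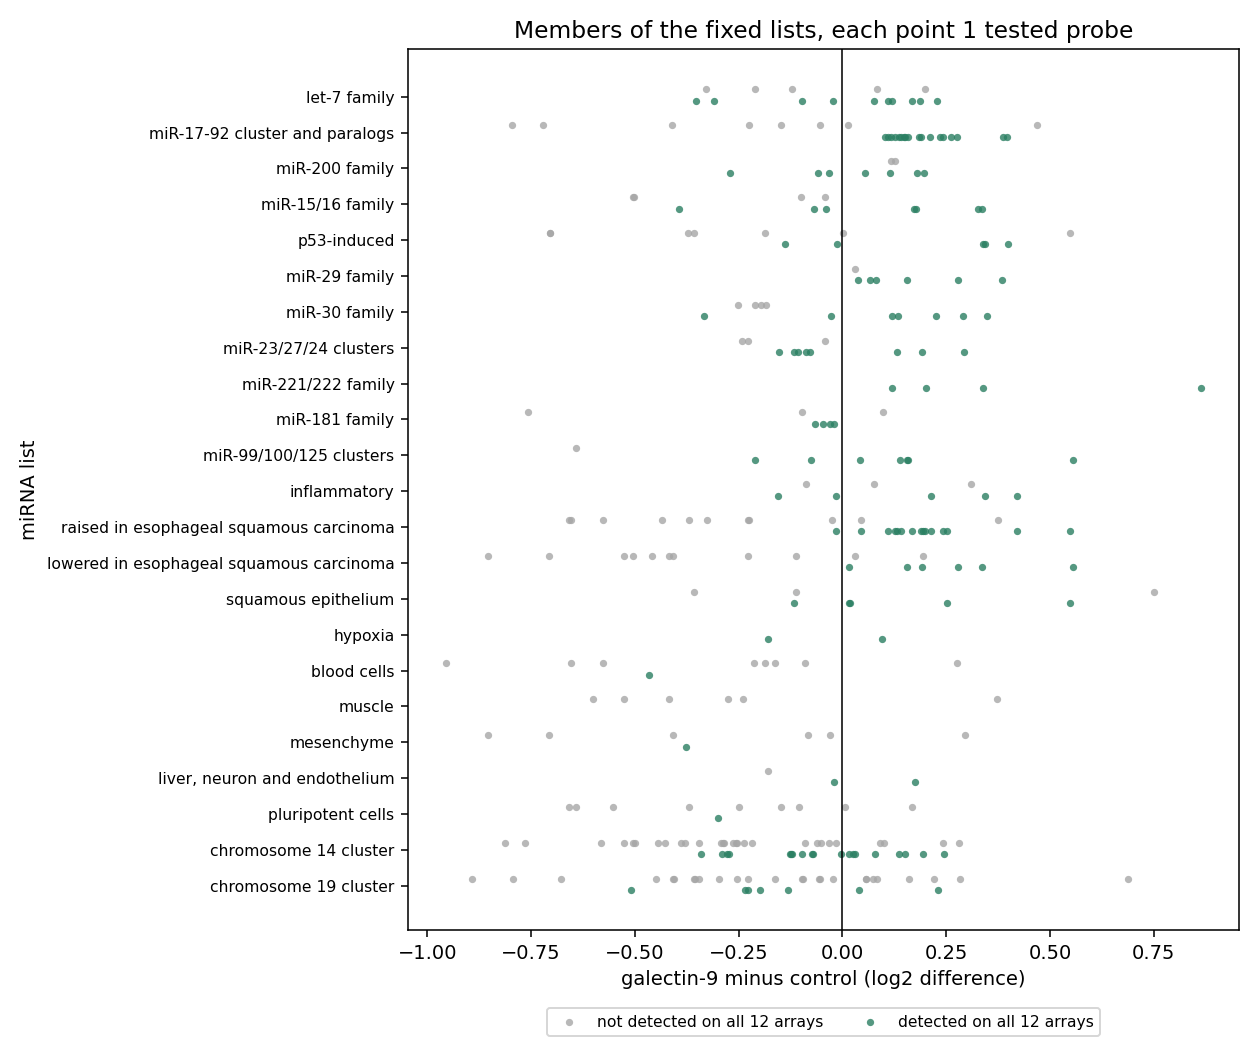
Log2 difference between galectin-9 and control (horizontal axis) for the tested members of 23 of the fixed lists (vertical axis), each point 1 probe. Green points are probes detected on all 12 arrays and grey points are dimmer probes. All 18 green points of the miR-17 cluster list lie above 0, while grey points lie mostly below 0, though not with a floor common to all arrays, where the median of the dim probes was 0.21.

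Markers of squamous epithelium did not pass (adjusted p = 0.0833), although 3 members passed when adjusted over the list alone. These were miR-31-3p (log2 difference 0.55), miR-31-5p (0.25) and miR-944 (0.75), a miRNA within the TP63 gene, each higher in 6 of 6 pairs. Over all probes tested none of them passed (limma adjusted p = 0.277, 0.271 and 0.277), and miR-31-3p and miR-31-5p are arms of 1 hairpin. Inflammatory miRNAs had an adjusted p of 0.0582, with miR-21-5p as the only member of the 8 tested past the threshold when adjusted over the list alone, which it no longer passed with the replicate block (adjusted p = 0.0687). Among the p53-induced miRNAs (adjusted p = 0.332), miR-215-5p (0.55) and miR-192-5p (0.40) passed when adjusted over the list alone, and both were higher in 6 of 6 pairs. Neither passed over all probes tested (limma adjusted p = 0.134 and 0.221). Of the 12 tested members 7 lay below 0, among them miR-34a-5p (-0.14), and miR-215-3p (-0.70) and miR-34b-3p (-0.70), both undetected on 5 arrays. With the block miR-194-5p (0.34) passed too (adjusted p = 0.0312).

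The miR-30 family had an adjusted p of 0.170, with 0 members past the threshold over the list alone. With the replicate block miR-30a-3p (0.35) passed over the list alone (adjusted p = 0.0464), and without it 1 member did among probes detected on all arrays. The adjusted p was 0.357 for the let-7 family, 0.430 for the miR-15/16 family and 0.698 for the miR-181 family. For the miR-200 family and for the miR-99, miR-100 and miR-125 clusters it was 0.218, with miR-99a-5p of the latter past the threshold over the list alone (adjusted p = 0.00681, and 0.0182 with the block), and for the miR-23/27/24 clusters 0.630. Members of the let-7 family went both ways, with -0.31 for let-7c-5p and 0.19 for let-7e-5p. For let-7c-5p, galectin-9 replicates 2, 4 and 6, all at position 4, had log2 intensities of 10.06 to 10.20. Replicates 1, 3 and 5 had 10.55 to 10.75, and controls 10.55 to 10.83. let-7d-5p had 10.40 in each of galectin-9 replicates 2, 4 and 6, against 11.22 to 11.49 in 1, 3 and 5 and 11.12 to 11.36 in controls. miR-30b-5p had 8.65, 9.31 and 8.56 in those at position 4, against 9.24 to 9.45 in the other galectin-9 arrays. let-7e-5p showed no such drop, with 8.70 to 8.92 against 8.65 to 8.76. The test pointed up while both the median and the mean lay below 0 for the p53-induced, miR-15/16, miR-30 and miR-23/27/24 lists, for the miRNAs lowered in oesophageal tumours and for the list of liver, neuron and endothelium. For the let-7 family only the mean did. The 2 arms of miR-210, the hypoxia list, were too few for the test.

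Lists for other cell types or imprinted and placental clusters did not pass. Their adjusted p was 0.332 for blood cells, 0.366 for muscle, 0.218 for mesenchyme, 0.630 for liver, neuron and endothelium and 0.155 for pluripotent cells. It was 0.272 for the chromosome 14 cluster and 0.332 for the chromosome 19 cluster. Their members were mostly dim, so that their values rest on the floor of each array, and in the lists for blood cells, muscle and mesenchyme only 1 probe each lay above 0. Passing when adjusted over the list alone were miR-150-3p in the blood list, miR-373-5p in the pluripotent list, and miR-519a-3p and miR-520h (-0.89) in the chromosome 19 list, all toward lower levels. These 4 no longer passed with the replicate block (adjusted p = 0.0751, 0.0775, 0.0659 and 0.0977), and miR-143-3p passed in the mesenchyme list (adjusted p = 0.0220). With an estimated correlation, 0 of the 24 lists passed. The counts with the replicate block were 5 lists with the preset and 0 with the estimated correlation, as without it.

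The arms of a hairpin come from the same precursor, and their changes were compared over 473 hairpins with both arms tested. The arms had the same sign of change in 55.8% of hairpins, against 52.3% with shuffled partners (permutation p = 0.0649, one-sided, adjusted p = 0.0774). Across hairpins, which are not independent replicates, Pearson's r was 0.102 (permutation p = 0.0263, two-sided, adjusted p = 0.0496) and Spearman's rho 0.0812 (permutation p = 0.0774, two-sided, adjusted p = 0.0774). Among 167 hairpins with both arms detected on all arrays, 58.1% had the same sign, against 50.4% with shuffled partners (permutation p = 0.0331, one-sided, adjusted p = 0.0496). There Pearson's r was 0.196 (permutation p = 0.0112) and Spearman's rho 0.172 (permutation p = 0.0260), both with an adjusted p of 0.0496. The adjustment is over these 6 tests. Partners were shuffled across all hairpins, early- and late-numbered together. Those classes differed in mean change, and both arms share a class, so a difference between classes may contribute.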

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

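The tests of brightness, of the main axes of variation between replicates and of a gradient along the slide were set out before their results were seen, and the comparison by parity of position after. In 9 of 120 groups of 6 arrays, a single array lay far from the other 5, where chance gives about 6. miR-222-3p was 9.80 (log2 intensity) in control 6, against 9.52 to 9.62 in the other controls. miR-31-5p stood apart in both arrays of replicate number 5, at 9.39 in control 5 (others 9.15 to 9.20) and 9.62 in galectin-9 replicate 5 (others 9.39 to 9.45). The other 5 of the miRNA values belong to the brightest probes, which quantile normalisation holds to a few fixed values. These were miR-7975 at 13.38 in galectin-9 replicate 1, miR-7977 at 13.05 in galectin-9 replicate 5, miR-1260b at 12.92 in control 4 and 13.38 in galectin-9 replicate 5, and miR-4284 at 13.05 in control 4. The mean log2 intensity of early-numbered minus late-numbered probes was 2.00 in control 5, against 1.66 to 1.78 in the other controls.

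That last measure differed between the groups within pairs. Early-numbered probes exceeded late-numbered ones by 1.76 ± 0.13 in control and 1.87 ± 0.18 in galectin-9 arrays (SD, n = 6 each, exact permutation p = 0.229), but by more with galectin-9 in 6 of 6 pairs (mean 0.11, exact sign-flip p = 0.0312, the smallest that 6 pairs allow). The pair difference stayed above 0 in 6 of 6 pairs with cyclic loess, normexp and the series table, and in 5 of 6 with median scaling. After a smooth trend on signal was removed, the mean was still 0.102 (6 of 6 pairs above 0). The values were already quantile-normalised, which removes most of such a trend, so this step could change little. It therefore does not decide on a bias that follows brightness, and with normexp the mean was 0.048. The main axes of variation between replicates are argued against, with a mean of 0.104 (6 of 6) after the 3 leading axes were removed. A steady gradient along positions 1 to 4 would need positions 3 and 4 to exceed positions 1 and 2, but their difference was -1.83 times that between the groups. Those positions also differ in replicate number, so this difference may come from either. An effect of odd against even position on the slide cannot be told apart from galectin-9, since 0 arrays share a parity with the other group, and a response to galectin-9 may equally account for it.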

How the results depend on the processing

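The replicate block combined with the filter for probes detected on all arrays was chosen after seeing the data. So were the blocks for slide and for positions 1 and 2 against 3 and 4 together. For lists, the common floor and the omission of control 6 were chosen after seeing the data too. The count of 3 changed miRNAs, 3 higher and 0 lower, stayed within 1.5 times with median and 75th percentile scaling, cyclic loess, no normalisation, no filter, a filter by group, a common floor, array weights and slide as a random block. It rose to 19 (13 higher, 6 lower) with normexp, to 14 (11 and 3) with a trend and robust variances, and to 9 (6 and 3) both over probes detected on all arrays and with the series table. It was 6 (4 and 2) with an unmoderated test and 5 (4 and 1) with slide as a fixed block. The count was the same with blocks for slide and for positions 1 and 2 against 3 and 4. With the replicate block it fell to 1 (1 higher, 0 lower), and with block and all-array filter it was 22 (14 and 8). The filter tests fewer probes, 891, but it also changed unadjusted p-values, which the number of tests does not alter. With the block, the limma unadjusted p of miR-6131 went from 2.08e-05 to 2.99e-06 under the filter. What moved the count in each case was not tested. Without slide 1, slide 2 or slide 3 it was 0, with fewer arrays and log2 differences for the 3 miRNAs that kept their direction. Leaving out single arrays gave 2 to 5 changed, 2 to 3 higher and 0 to 2 lower, with the 5 reached without galectin-9 replicate 1. Under 33 alternatives, miR-6131 kept its direction in 33 and its call in 30, miR-222-5p in 33 and 29, and miR-582-5p in 33 and 19, with adjusted p up to 0.308, 0.496 and 0.499. Their log2 differences, 1.18, 0.86 and 0.61, ranged over 0.49 to 1.28, 0.15 to 0.96 and 0.10 to 0.69, smallest with normexp, whose offset of 50 shrinks dim values. Over all named miRNAs and alternatives, 44 calls were gained, 21 were lost, all by these 3 miRNAs, and 0 calls turned in direction. Changes of sign in miRNAs called under neither setting were not counted as turns. The median log2 difference of the tested probes was -0.07 with quantile normalisation, -0.01 with median scaling and 0.06 without normalisation or with a common floor. The 5 called lists numbered 4 to 7 under the other 8 settings and 0 with an estimated correlation. There the adjusted p was 0.376 for the miR-17 cluster, 0.114 for miR-29, 0.0962 for miR-221 with miR-222, 0.471 for the list raised in oesophageal tumours and 0.488 for early-numbered miRNAs, and the miR-29 list also lost its call with the common floor (0.183) and without control 6 (0.113). Among members adjusted over their list alone, the replicate block ended 8 calls and added 9, while 11 passed either way. It changed no call of a list as a whole. The share of hairpins with arms of the same sign was 52.0% to 58.1%, and the difference in detected probes went from 251 to 217 with a limit of 3 SD over the blanks, within the spread between arrays in either case. The signal over background limits the dim probes, since 843 of 1734 tested probes were below the detection limit on at least 1 array.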

Other observations

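The comparisons by parity of position and with a common floor, and the 22 calls with block and filter, were set out after the data were seen. Those 22 calls include miRNAs besides the 9 called without the block, of which miR-31-3p, miR-192-5p and miR-30a-3p were also named as members of fixed lists. miR-4639-5p was lower (log2 difference -1.04, limma adjusted p = 0.00948) and miR-31-3p higher (0.55, limma adjusted p = 0.00948), each in 6 of 6 pairs. Higher too were miR-6087 (0.75), miR-4317 (0.47), miR-135b-5p (0.45), miR-711 (0.40), miR-192-5p (0.40), miR-30a-3p (0.35) and miR-598-3p (0.34). The lower ones include miR-3614-5p (-0.44), miR-346 (-0.36), miR-6089 (-0.36) and miR-6777-5p (-0.28). The others were named after their values were seen.

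The 3 miRNAs that passed exceed what other groupings of the arrays gave. Of 100 splits of the 12 arrays into groups of 6, drawn from 462, 1 gave 3 or more calls, the real one, and the highest of the others gave 2. Of the 32 splits that part all 6 pairs, 1 gave as many, again the real one, and the highest other gave 0. With block and filter, chosen after the data were seen, 1 of 32 gave 22 or more calls, and the highest other gave 0. The real split is 1 of these 32, the smallest share they allow, so chance is unlikely but not excluded. As a check for a steady gradient, the difference of positions 3 and 4 from 1 and 2 was set against that between the groups. It was 0.0125 times as large (median of the 3), and 0.267 times for miR-6131. A large ratio would widen the spread within groups, and a probe with a wide spread is unlikely to be called. The low ratio was therefore largely set by the choice of called probes, and it does not decide on a gradient. These positions also differ in replicate number, which limits the comparison further. Odd against even position on the slide cannot be told apart from galectin-9, with 0 arrays at a shared parity, so that position or treatment may underlie the rise.

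The list calls with the preset correlation do not stand out in the same way. Of the 100 splits, 21 called 5 or more lists, and the highest of the others called 10. Of the 32 splits that part every pair, 4 called as many, with 6 as the highest other, so chance cannot be excluded for the number of lists. The split by positions 1 and 2 against 3 and 4 called 7 lists and 0 probes, within what the other splits gave. With the replicate block, which holds slide and these positions fixed, 5 lists were called.

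Dim probes lay lower with galectin-9: of the 843 tested probes not detected on all arrays, 606 were lower and 237 higher, with a median log2 difference of -0.17. The floor of each array is a candidate cause, since with a common floor the median was 0.21, of the opposite sign. The floor averaged 1.13 ± 0.83 in control and 0.50 ± 0.62 in galectin-9 arrays (log2, SD, n = 6 each, exact permutation p = 0.173). Without control 6, the array with the fewest detected probes, the median was -0.0542, which lies between what that array alone and a wider cause would give. These medians leave the direction of the dim probes as a class undetermined.

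A further hypothesis was that hairpins from the same genomic cluster, taken as genes at most 10000 bases apart, change together. Over 115 hairpins in 41 clusters the intraclass correlation was 0.180 (permutation p = 0.0385), as shared transcription would predict. The shuffling did not keep early- and late-numbered hairpins apart. These classes differed in mean change, so a difference between them may contribute. Without the miR-17 cluster list, 105 hairpins in 38 clusters gave an intraclass correlation of 0.120 (permutation p = 0.134). Similar sequences within a cluster, which can share signal between probes, were not tested.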
